A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

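RNA from wild-type budding yeast of strain BY4741 was compared between potassium-free medium and the same medium with 50 mM KCl, 10, 20, 40, 60 and 120 min after the shift. Per the labels, cells were grown at 28 °C to an absorbance of 0.6, 8 µg of RNA was labelled indirectly through a modified dUTP, and spots under 120 µm in diameter or under 100 intensity units were left out. The deposited values are log2 ratios of the channels of an array, 1 value per gene and array. That they are log2 was taken from their range, since some sizes exceed what other log bases allow. Against a natural log this rests on replicate 4 of 120 min, with 3 values at 15.73. On the other arrays the most extreme value was -8.38. The base, and the folds drawn from it, are thus likely and not stated. Background correction and normalization are not given in the sources used here. The direction, potassium-free over KCl, is likely from the array titles and not stated. All pairs of the 18 arrays correlated above 0 across genes (lowest r = 0.0416), dye swaps included, so the ratios had been turned the same way before deposit. On 1 array at 10 min both channels are labelled with the same dye in the labels, and its title was followed.

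The table held 6212 genes, of which 439 had no value and 2545 had values on all 18 arrays. Gene IDs are systematic open reading frame names; 5644 matched a RefSeq locus tag of assembly R64 exactly and 18 more after writing them in capitals, and 550 kept their ID. No genome build is named for the arrays, so no positions are given. Array medians ran from -0.237 to 0.179, and the arrays held values for 3913 to 5372 genes. Within a time point, pairs of arrays correlated across genes with r = 0.534 at 10 min, 0.229 to 0.644 at 20 min, 0.607 to 0.853 at 40 min, 0.803 to 0.945 at 60 min and 0.758 to 0.878 at 120 min. For arrays, their number limits the precision.

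The labels state 2 independent experiments with a dye swap each at 20, 40, 60 and 120 min and 1 at 10 min, without saying which arrays belong together. Arrays 1 and 2 were taken as experiment A and 3 and 4 as experiment B; the other pairing with opposite dyes, 1 with 3 and 2 with 4, was an alternative. The consensus correlation of arrays within an experiment was 0.252 in the pairing used and -0.236 in the other. Each dye-swap pair was averaged, since it compares the same RNAs, giving 9 experiment values per gene. A gene was tested at a time point if at least 3 of 4 arrays, or both at 10 min, had a value.

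The values were fitted as deposited in limma 3.58.1 under R 4.3.3 with a mean per time point, and a moderated test against 0 used a spread shared by all time points (prior degrees of freedom 3.49, residual degrees of freedom 4). At 10 min the lone experiment is assumed to vary like the others. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, all tests are two-sided, and the threshold was 0.05. A moderated F test asked which genes differ between 20, 40, 60 and 120 min, and a contrast compared 120 with 20 min. The p-values rest on the spread between 2 experiments per time point. Counts given as adjusted over the list alone use the Benjamini-Hochberg adjustment within a gene list.

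Gene lists were tested with cameraPR in limma at a preset correlation of 0.01, adjusted over all 146 pairs of a list and a time point with at least 4 measured members. The test was repeated in camera with an estimated correlation and in fry. The 31 lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text draws on the 8 highest and 8 lowest genes past the threshold with 1 sign on every array at 20 to 120 min, filled with the next largest means where fewer passed, and on the 5 highest and 5 lowest at 10 min. It also takes the 5 largest rises and 5 largest falls from 20 to 120 min, up to 4 members of each list with the largest means, and 10 fixed genes: TRK1, TRK2, ENA1, PMA1, PHO84, ACT1 and the 4 genes deleted in BY4741. Some genes that the rule takes are not reported here.

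The alternatives were the other pairing, each array as a replicate, the experiment as a random block, a dye term, a replicate block, median centring, scaling of the arrays to the same median absolute value, quantile normalization, stricter and looser filters, a robust prior and other thresholds. Each array and each experiment was also left out in turn. Chosen after seeing the data were fits of each time point alone, fits without replicate 3 of 40 min or replicate 4 of 120 min, a fit without values at a shared maximum, and differences between neighbouring time points.

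The procedure was tested on simulated data with the moderated spread of each gene from the fit, shared by all time points, and with genes drawn independently. Of 68 genes changed by a log2 value of 1, 60.3% were recovered at 20 min (4361 genes), 70.6% at 60 min (4127 genes) and 57.4% at 120 min (4410 genes), and of 66 changed by 2, 100% were recovered at 20 and 60 min and 97.0% at 120 min. Unchanged genes made up 4.95%, 5.76% and 5.06% of the calls. For the contrast of 120 with 20 min 71.8% of 387 changed genes were recovered (3978 genes), and for the F test 62.6% of 655 (3714 genes). A shift of -0.30 put into the ribosomal protein list at 40 min was recovered as -0.28, with 0 of 145 other pairs called. As the simulated genes were independent, this says nothing about false calls among lists of correlated genes. The simulation also built in the shared spread that the fit assumes. In the measured data the SD of the difference between experiments was 0.423 at 20 min and 0.746 at 120 min. Rates of false calls under such unequal spreads were not tested. The estimated correlation of the ribosomal protein list was 0.804 in the measured data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.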

Results

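Spotted DNA microarrays with a dye for each RNA were used to compare messenger RNA between cultures of wild-type BY4741, a laboratory strain of budding yeast, that had been moved to a medium without added potassium and parallel cultures that received 50 mM KCl in the same medium. The potassium-free medium held about 15 µM residual potassium. Cells were taken 10, 20, 40, 60 and 120 min after the shift, and the series asks how the transcriptome responds to a sudden shortage of external potassium. Each array held both RNAs of a time point, so each value is a log2 ratio of potassium-free over KCl cells. That direction is likely and not stated: it is the order in the array titles, and the measured ratios of arrays with opposite dyes run the same way. There were 18 arrays: 2 at 10 min (1 experiment with its dye swap) and 4 at each later time point (2 independent experiments with a dye swap each). The arrays gave values for 3913 to 5372 genes each, and their number limits the precision. Errors below are standard errors (SE) of the mean of the experiments, from a limma fit over all 9 experiments.

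The ratios spread more widely at 40, 60 and 120 min than at 10 and 20 min. The standard deviation (SD) over genes was 0.403 and 0.443 on the 10 min arrays, 0.384 to 0.555 at 20 min, 0.612 to 0.905 at 40 min, 1.06 to 1.30 at 60 min and 0.839 to 1.45 at 120 min. Across genes, which are not independent replicates, the experiments of a time point correlated with r = 0.461 at 20 min, 0.739 at 40 min, 0.848 at 60 min and 0.836 at 120 min. The number of genes past an adjusted p of 0.05 was 0 at 10 min, 21 at 20 min, 420 at 40 min, 1932 at 60 min and 1867 at 120 min. These counts use a spread shared by all time points. The SD of the difference between experiments was 0.423, 0.505, 0.669 and 0.746 at 20, 40, 60 and 120 min. Fits of these time points alone, chosen after seeing the data, gave 65, 996, 1350 and 646 genes. Counts and their order over time thus depend on the shared spread. Of 156 values of named genes past the threshold, 11 did not pass without 1 of the arrays; of the 146 for which an experiment could be left out, 54 did not pass without 1 or the other, and the remaining experiment was then assumed to vary like those of other time points. Ratios are relative to the rest of each array, so a change in total messenger RNA per cell would not show.

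**Figure D1:**
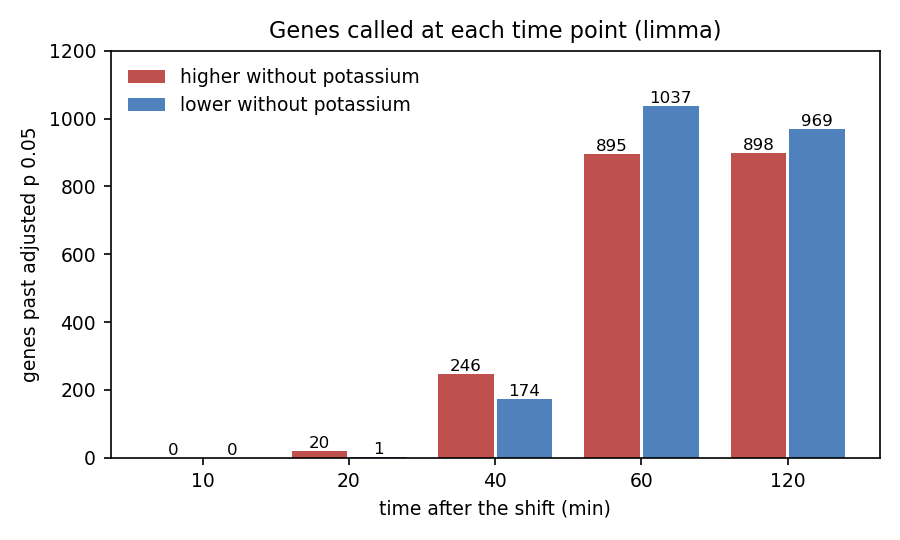
Number of genes past an adjusted p of 0.05 (y axis) at each time after the shift (x axis, min), higher (red) or lower (blue) without potassium. The bars go from 0 genes at 10 min to 895 higher and 1037 lower genes at 60 min.

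At 10 min the highest mean log2 ratios belonged to SUL2, a high-affinity sulfate permease (3.01), CIT2, the peroxisomal citrate synthase (2.69), STR3, a cystathionine beta-lyase (2.49), MET3, ATP sulfurylase (2.38), and AGA1, an anchor of a-agglutinin (2.15). The lowest were SUE1 (-3.55), the small heat shock protein gene HSP26 (-2.92), the aromatic aminotransferase gene ARO9 (-2.75), the HSP70 gene SSA4 (-1.98) and the cohesin gene MCD1 (-1.74). All 10 had the same sign on both arrays, and none passed the test (adjusted p = 0.123 for CIT2 and SUE1, 0.524 for SUL2). With 1 experiment there was no replicate, so this and the p-values that follow rest on a spread taken from the later time points and show no change beyond this experiment. Of the fixed gene lists, sulfate assimilation and methionine or cysteine synthesis had a median of 0.92 over 28 genes, with 0 members past the threshold over all genes tested and 12 past it, above 0, when adjusted over the list alone (camera adjusted p = 1.6e-51; adjusted p = 0.257 with an estimated correlation). The phosphate starvation list had a median of 0.46 over 16 genes, with 5 past the threshold and above 0 when adjusted over the list alone (camera adjusted p = 7.89e-11; adjusted p = 0.463 with an estimated correlation). The list of genes deleted in BY4741 also passed at 10 min, with a median of 0.475. In this fit limma called 0 of 4821 genes, with 135 at an unadjusted p under 0.05. With the arrays taken in other ways limma called 4 genes with the other pairing of arrays, 39 with each array as a replicate, 22 with a dye term, 7 with the experiment as a random block, 76 with the arrays scaled to the same spread (43 higher, 33 lower) and 115 after quantile normalization (71 higher, 44 lower).

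At 20 min the 21 genes past the threshold were mostly genes of sulfur uptake and methionine synthesis. MET17, also a gene of methionine synthesis, is deleted in BY4741, so both cultures on each array lacked it. STR3 was 14.8-fold higher (log2 3.89 ± 0.25, adjusted p = 0.00222, 2 experiments), and MET1 (2.57 ± 0.21), MET28 (2.37), MET3 (2.28), MET14 (2.22), MET16 (1.85), MET5 (1.57) and MET10 (1.19) rose with it. The permease genes SAM3 (1.94), MMP1 (1.88) and MUP1 (1.72), which carry S-adenosylmethionine, S-methylmethionine and methionine, also rose. In all, 11 of the 25 measured members of the sulfur list rose and 0 fell, 20 rose when adjusted over the list alone. The median was 1.35 (camera adjusted p = 2.36e-93 and adjusted p = 0.257 with an estimated correlation). With the arrays scaled to the same spread it was 2.34, and after quantile normalization 2.48. The retrograde response genes CIT2 (3.66 ± 0.26, adjusted p = 0.00222) and DLD3, a lactate dehydrogenase (2.24), were higher, as were the phosphate starvation genes PHO12 (1.62), PHO11 (1.57) and PHO84, the high-affinity phosphate transporter (1.15). The others were YRO2 (2.36), YLR108C (1.62), ICY1 (1.59) and TPO2, a polyamine transporter (1.12). The catabolic serine and threonine deaminase gene CHA1 was the lone gene that fell (-1.55 ± 0.22, adjusted p = 0.0356). MCD1 (-2.35, adjusted p = 0.0674), the amino acid permease gene GAP1 (-2.13, adjusted p = 0.0687) and the ribonucleotide reductase gene RNR1 (-1.94, adjusted p = 0.793) were below 0 on every array that measured them without passing.

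The phosphate list had 3 of 16 members higher at 20 min, 6 when adjusted over the list alone. Signal shared between probes of related genes, such as PHO11 and PHO12, was not checked. Calls of such members may therefore not be separate, here or at later time points. Over the list the median was 0.47 (camera adjusted p = 4.11e-15; adjusted p = 0.463 with an estimated correlation). The retrograde and citrate cycle list had 2 of 19 higher, CIT2 and DLD3, and 3 when adjusted over the list alone. The members' median was 0.29, with 0.50 in experiment A and 0.22 in B (camera adjusted p = 2.01e-08; adjusted p = 0.334 with an estimated correlation). Of the 26 measured G1 and S phase genes 0 passed over all genes and 7 fell when adjusted over the list alone. The list stood at a median of -0.69 (camera adjusted p = 8.22e-09; adjusted p = 0.463 with an estimated correlation). The count at 20 min was sensitive to the scale: 312 genes passed (158 higher, 154 lower) once all arrays were given the same spread and 376 (186 higher, 190 lower) after quantile normalization, against 20 higher and 1 lower as deposited, 88 with the other pairing and 1 or 3 with either experiment left out. Without replicate 1 of 20 min MET28, PHO84, TPO2 and ICY1 no longer passed (adjusted p = 0.0896, 0.0758, 0.243 and 0.0758), nor did CHA1 without replicate 2 (0.0726) or MET10 without replicate 2, 3 or 4 (0.0817, 0.0688, 0.0842).

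At 40 min 246 genes were higher and 174 lower. The sulfur genes held the highest mean: SUL2 was 17.8-fold higher (log2 4.15 ± 0.47, adjusted p = 0.00532), with MET3 at 3.85, MET14 at 3.76, MET28 at 3.64 and STR3 at 3.56 (4.19 without replicate 3 and 2.94 without replicate 4). Of 27 measured sulfur genes 20 rose, 25 when adjusted over the list alone, and 0 fell. Across members the median was 1.45 (camera adjusted p = 2.99e-57; adjusted p = 0.324 with an estimated correlation). General stress genes of the Msn2 and Msn4 type appeared among the calls, with 21 of 30 higher and 0 lower, 24 higher when adjusted over the list alone. Their median was 1.49, with 1.86 in experiment A and 1.05 in B (camera adjusted p = 1.38e-18; adjusted p = 0.463 with an estimated correlation). They included the hydrophilin gene GRE1 (3.70 ± 0.57, or 2.48 without replicate 1), RTC3 (3.26), the aldo-keto reductase gene GCY1 (3.02) and the aldehyde dehydrogenase gene ALD3 (2.81); the transaldolase paralog NQM1 stood at 4.08. Trehalose and glycogen genes had 8 of 18 higher, 10 when adjusted over the list alone, with TPS2, trehalose-6-phosphate phosphatase, at 2.11. The list median was 1.11, with 1.43 in experiment A and 0.76 in B (camera adjusted p = 1.87e-05; adjusted p = 0.494 with an estimated correlation). In the phosphate list 8 of 16 rose, 9 when adjusted over the list alone, among them the acid phosphatase gene PHO5 (2.17), PHO11 (1.95) and PHO84 (1.44). The median was 0.76 (camera adjusted p = 5.41e-08; adjusted p = 0.464 with an estimated correlation).

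Among the genes that fell at 40 min, MCD1 (-2.53 ± 0.35, adjusted p = 0.0148), the efflux transporter gene AQR1 (-2.48), the RNA helicase gene DBP2 (-2.26), the G1 cyclin gene PCL1 (-2.17), TOS6 (-2.15), YGR079W (-2.14) and the bud neck kinase gene KCC4 (-2.14) were among the 8 with the lowest means. TOD6 (-2.47), a repressor of ribosome biogenesis genes, was the other and did not pass without replicate 2 or 3 (adjusted p = 0.141 and 0.0971). Of 89 ribosome biogenesis genes 24 fell and 1 rose, and 73 fell when adjusted over the list alone. Over the list the median was -1.09 (camera adjusted p = 5.69e-19; adjusted p = 0.463 with an estimated correlation). The genes of the ribosomal proteins themselves stood nearer to 0: 1 of 124 fell over all genes, 0 when adjusted over the list alone. The members' median was -0.26, with -0.57 in experiment A and 0.08 in experiment B, and -0.43 without replicate 3 (camera adjusted p = 0.00614; adjusted p = 0.694 with an estimated correlation). The core histone list also holds the variant gene HTZ1 and the linker histone gene HHO1. It had 4 of 10 lower, 8 when adjusted over the list alone, including HTB2 (-1.56) and HTA2 (-1.47). The list stood at a median of -0.73 (camera adjusted p = 3.98e-05; adjusted p = 0.463 with an estimated correlation). G1 and S phase genes had 11 of 30 lower and 1 higher, 13 lower and 1 higher when adjusted over the list alone. Across members the median was -0.95, with -0.59 in experiment A and -1.21 in B, and -0.46 over genes on all 18 arrays (camera adjusted p = 3.66e-08; adjusted p = 0.463 with an estimated correlation). SER3 (3.27) and SER33 (1.95), isozymes of the first step of serine synthesis, were higher, and so were CIT2 (3.36), the pyruvate carboxylase gene PYC1 (2.01) and the protein kinase gene PTK2, an activator of the plasma membrane proton pump (1.42). Replicate 3 of 40 min had the widest spread of the 4 arrays, and 271 genes passed without it, with the nucleolar gene NSR1 (-1.93) no longer among them (adjusted p = 0.0616). With the other pairing of arrays 1244 genes passed, with either experiment left out 24 or 41, after scaling the arrays to the same spread 701 (357 higher, 344 lower) and after quantile normalization 829 (410 higher, 419 lower).

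**Figure D2:**
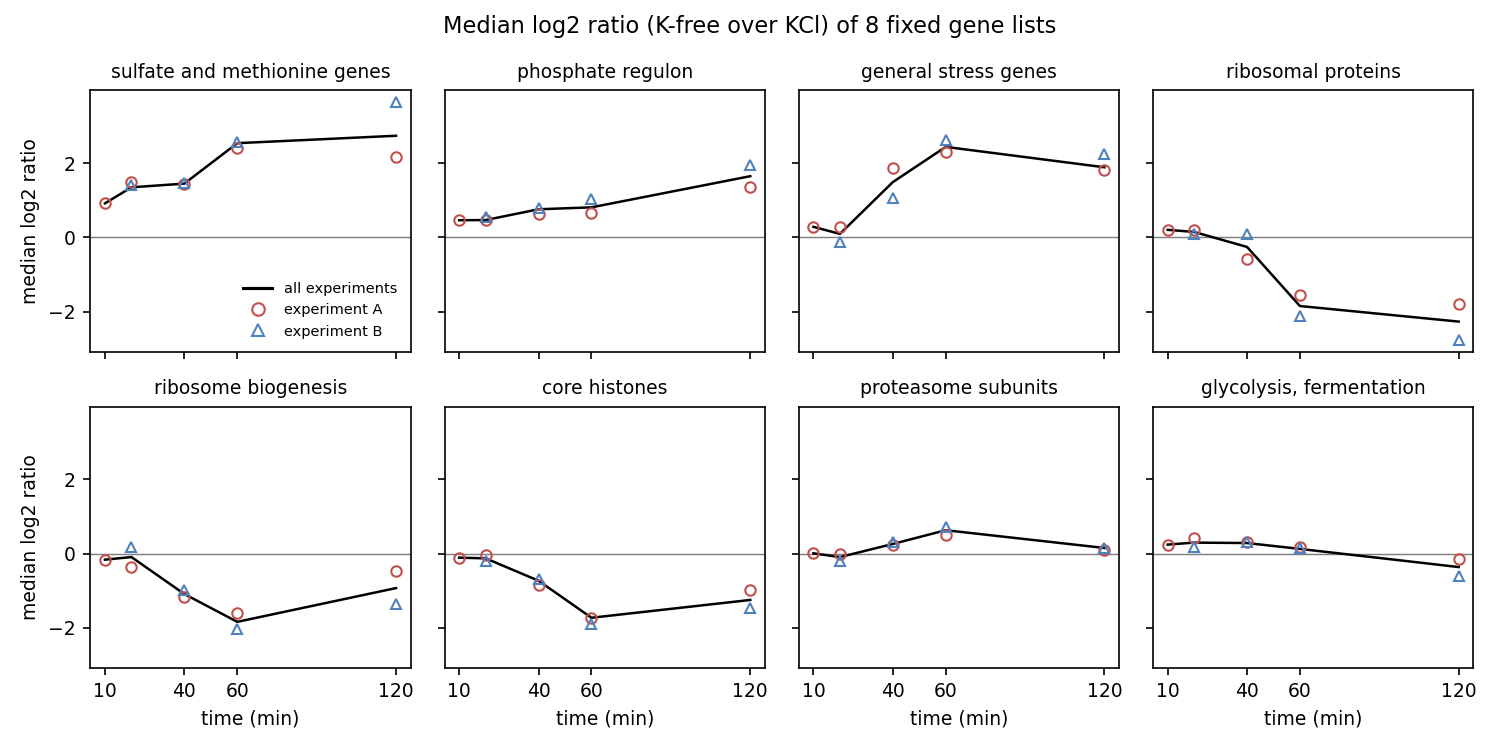
Median log2 ratio (y axis) of the measured genes of 8 fixed lists against time (x axis, min), for experiment A (circles), experiment B (triangles) and the mean of the experiments (line). The ribosome biogenesis median was -1.09 at 40 min, when that of the ribosomal proteins was -0.26 (-0.57 and 0.08 in the experiments), and at 120 min the medians were -0.93 and -2.27.

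At 60 min 895 genes were higher and 1037 lower, 1157 of them by at least 2-fold. GRE1 was 96.6-fold higher (log2 6.59 ± 0.57, adjusted p = 0.000623), SUL2 85.9-fold (6.42 ± 0.47, adjusted p = 0.000309) and CIT2 48.8-fold (5.61 ± 0.26, adjusted p = 3.87e-05), followed by the methionine permease gene MUP3 (5.41, or 6.55 without replicate 1), MET3 (5.26), the hydrophilin gene SIP18 (5.20, or 3.71 without replicate 2), NQM1 (4.92) and STR3 (4.88). Of 26 measured sulfur genes 25 rose, 26 when adjusted over the list alone. Their median was 2.54 (camera adjusted p = 5.94e-40 and adjusted p = 0.324 with an estimated correlation). With the arrays scaled to the same spread it was 1.62, and after quantile normalization 1.75. Both lay below the values of 20 min in the same settings, so a rise from 20 to 60 min depends on the scale. General stress genes had 27 of 32 higher and 1 lower, 28 higher and 1 lower when adjusted over the list alone, with ALD3 at 4.24 and GCY1 at 4.23. The list median was 2.44 (camera adjusted p = 5.17e-17; adjusted p = 0.463 with an estimated correlation). The reading frame YOR121C, which overlaps GCY1 on the other strand and was picked out after its values were seen, stood at 4.24, and transcripts of the pair were not told apart here. Trehalose and glycogen genes had 15 of 17 higher, also 15 when adjusted over the list alone, led by the phosphoglucomutase gene PGM2 (3.63) and the glycogen branching enzyme gene GLC3 (3.37). The median was 2.42 (camera adjusted p = 3.66e-08; adjusted p = 0.476 with an estimated correlation). Heat shock chaperones had 11 of 20 higher and 0 lower, 12 higher when adjusted over the list alone, led by SSA4 (4.02) and HSP104 (3.32). Over the list the median was 0.62 (camera adjusted p = 0.000556; adjusted p = 0.463 with an estimated correlation). Of 30 proteasome genes 19 rose and 2 fell, 23 and 2 when adjusted over the list alone, by modest amounts such as 1.14 for RPN5 and 1.09 for RPT4. The members' median was 0.63 (camera adjusted p = 0.000855; adjusted p = 0.463 with an estimated correlation).

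The translation machinery fell at 60 min. All 119 measured cytosolic ribosomal protein genes were lower over all genes tested and when adjusted over the list alone, with a median of -1.85, RPS9B and RPS22A at -2.50 and RPL9A at -2.39 (camera adjusted p = 4.43e-26; adjusted p = 0.477 with an estimated correlation). Ribosome biogenesis genes had 79 of 87 lower and 2 higher, 80 and 3 when adjusted over the list alone, among them ALB1 (-3.65), which belongs to the pathway but not to the list, and the listed YTM1 (-3.44), DBP2 (-3.25) and NSR1 (-3.22). The list stood at a median of -1.84 (camera adjusted p = 2.16e-17 and adjusted p = 0.464 with an estimated correlation). With the arrays scaled to the same spread the ribosomal protein and biogenesis medians were both -1.1. After quantile normalization they were -1.2 and -1.23. RNA polymerase I and III subunits had 12 of 16 lower, 13 when adjusted over the list alone, with RPA34 at -2.83 and RPA12 at -2.63. Across members the median was -0.95 (camera adjusted p = 9.16e-05; adjusted p = 0.476 with an estimated correlation). All 10 genes of the core histone list fell, also when adjusted over the list alone, with HTB2 at -3.75 and HTA2 at -3.11. Their median was -1.73 (camera adjusted p = 8.22e-09; adjusted p = 0.463 with an estimated correlation). G1 and S phase genes had 14 of 24 lower and 1 higher, 17 and 1 when adjusted over the list alone, with TOS4 at -3.80 and PCL1 at -3.56; YOX1 was at -3.69, and at -5.71, -4.40 and -2.98 without replicates 1, 3 and 4. The list median was -1.27 (camera adjusted p = 9.37e-05; adjusted p = 0.477 with an estimated correlation), and -0.62 over genes measured on all 18 arrays, where the list did not pass (adjusted p = 0.0748). TOS6 was at -4.13. MKC7, a membrane protease gene, had the lowest mean (-4.77), which rested on replicate 3 at -8.38, its only value in experiment B. Without that replicate experiment A alone remained, at -1.17.

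Further lists passed or held large single changes at 60 min. The phosphate list had 10 of 15 higher and 1 lower, the same numbers when adjusted over the list alone, with PHO5 at 2.36 and the vacuolar phosphatase gene PHO8 at 1.86. The median was 0.81 (camera adjusted p = 0.00414; adjusted p = 0.498 with an estimated correlation). The retrograde and citrate cycle list had 10 of 16 higher and 2 lower, the same numbers when adjusted over the list alone. Over the list the median was 1.06 (camera adjusted p = 2.6e-05; adjusted p = 0.463 with an estimated correlation). Calcineurin-type targets had 7 of 11 higher, also 7 when adjusted over the list alone, with the calcineurin regulator gene RCN2 at 2.22. The members' median was 1.29 (camera adjusted p = 0.00509; adjusted p = 0.463 with an estimated correlation). Ergosterol synthesis had 11 of 22 lower and 0 higher, 12 lower when adjusted over the list alone, with ERG3 at -2.54 and ERG25 at -1.97. The list stood at a median of -0.54 (camera adjusted p = 0.00775; adjusted p = 0.498 with an estimated correlation). Cell wall integrity genes had 11 of 23 higher, such as PIR3 (3.10) and PST1 (2.66), and 5 lower, such as the glucanosyltransferase gene GAS1 (-2.27), 11 and 6 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.173). The iron regulon had 3 of 19 higher and 3 lower, also when adjusted over the list alone: the heme oxygenase gene HMX1 was at 3.67, the siderophore transporter gene SIT1 at -2.82 and the iron permease gene FTR1 at -2.56 (camera adjusted p = 0.857). Hexose transporter genes had 3 of 12 higher and 1 lower, also when adjusted over the list alone, with HXT5 at 3.55 and HXT2 at -2.66 (camera adjusted p = 0.401); the hexokinase gene HXK1 was at 3.02. Amino acid synthesis genes of the Gcn4 type had 8 of 41 higher and 8 lower, also when adjusted over the list alone, with SER3 at 4.10 and SER33 at 3.15 (camera adjusted p = 0.368). The inosine monophosphate dehydrogenase genes IMD4 (-3.09) and IMD3 (-2.85) fell; they are near-identical paralogs whose probes may share signal, as may those of ribosomal protein pairs. The count was 990 without experiment B of 60 min, 1937 with each array centred on its median (987 higher, 950 lower), 1157 after scaling the arrays to the same spread and 1145 after quantile normalization.

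At 120 min 898 genes were higher and 969 lower. GRE1 was 95.3-fold higher (log2 6.58 ± 0.57, adjusted p = 0.00108), and NQM1 (4.86 ± 0.51), HSP26 (4.66 ± 0.64), SUL2 (4.63), AGA1 (4.52), MET10 (4.43), MOH1 (4.41, or 3.54 without replicate 3) and MET3 (4.39) followed. The fold of GRE1 was 55.6 without replicate 4 and 164 without replicate 3. Of 27 measured sulfur genes 23 rose, also 23 when adjusted over the list alone. Across members the median was 2.74, with 2.18 in experiment A and 3.64 in B, and 1.78 over genes on all 18 arrays (camera adjusted p = 3.42e-38; adjusted p = 0.324 with an estimated correlation). The phosphate list had 11 of 16 higher and 1 lower, the same numbers when adjusted over the list alone, with PHO84 at 3.44 ± 0.17 (10.8-fold, adjusted p = 8.08e-05) and the glycerophosphoinositol transporter gene GIT1 at 3.03. Their median was 1.65 (camera adjusted p = 1.42e-07; adjusted p = 0.463 with an estimated correlation). General stress genes had 27 of 32 higher, 28 when adjusted over the list alone, with the transketolase gene TKL2 at 3.89 (4.68 without replicate 3 and 3.11 without replicate 4). The list median was 1.89 (camera adjusted p = 3.36e-15; adjusted p = 0.463 with an estimated correlation). Trehalose and glycogen genes had 14 of 18 higher, 15 when adjusted over the list alone, with GLC3 at 2.55. The median was 1.51 (camera adjusted p = 0.000348; adjusted p = 0.498 with an estimated correlation). The a-mating-type genes, which match the mating type of BY4741, had 5 of 5 higher, also when adjusted over the list alone, with ASG7 at 3.52 and AGA2 at 3.10. Over the list the median was 1.88 (camera adjusted p = 2.14e-06; adjusted p = 0.463 with an estimated correlation). Calcineurin-type targets had 6 of 11 higher and 0 lower, 6 and 1 when adjusted over the list alone, with the glucan synthase gene GSC2 at 2.38. The members' median was 0.93 (camera adjusted p = 0.0339; adjusted p = 0.464 with an estimated correlation).

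The lowest gene at 120 min was INO1, inositol-3-phosphate synthase (20.3-fold lower, log2 -4.35 ± 0.56, adjusted p = 0.00177). It was 34.7-fold lower without replicate 4 and 11.9-fold lower without replicate 3. YAR073W (-3.48) and IMD3 (-3.05), both of the inosine monophosphate dehydrogenase family, RPS22A (-3.21), RPL9A (-3.11), RPS9B (-3.05), the telomeric helicase gene YRF1-6 (-3.04) and CHA1 (-2.97) followed. YRF1-6, of a family of near-identical copies, had an adjusted p of 0.0564 without replicate 1 and a mean of -1.09 without replicate 3. Of 116 ribosomal protein genes 114 fell, also when adjusted over the list alone. The list stood at a median of -2.27, with -1.79 in experiment A and -2.76 in B (camera adjusted p = 3.08e-47; adjusted p = 0.464 with an estimated correlation). Ribosome biogenesis genes had 43 of 80 lower and 3 higher, the same numbers when adjusted over the list alone, with UTP6 at -2.09. Across members the median was -0.93, with -0.48 in experiment A and -1.37 in B (camera adjusted p = 3.01e-05; adjusted p = 0.559 with an estimated correlation). Histones had 9 of 10 lower, also when adjusted over the list alone. Their median was -1.25 (camera adjusted p = 1.69e-05; adjusted p = 0.463 with an estimated correlation). G1 and S phase genes had 13 of 23 lower and 2 higher, 15 and 3 when adjusted over the list alone (median -1.01, camera adjusted p = 0.00773; adjusted p = 0.559 with an estimated correlation; -0.80 and not past the threshold over genes on all 18 arrays, adjusted p = 0.213), and the mitotic cyclin gene CLB1 was at -2.44. Lists that did not pass at 120 min held large single changes: PIR3 was at 3.47, HMX1 at 3.14, SSA4 at 2.93, the glucose transporter gene HXT4 at 2.79, the proline oxidase gene PUT1 at 2.48 and SER3 at 3.54. Without replicate 3 HMX1 was at 3.76 and PUT1 at 3.24, and without replicate 4 they were at 2.53 and 1.71. The pyruvate decarboxylase isozyme gene PDC6 was at 3.96 ± 0.71, or 2.97 without replicate 4 and 4.95 without replicate 3, and DLD3 at 2.62. The proteasome list, 3 of 31 higher and 2 lower here and when adjusted over the list alone, did not pass (camera adjusted p = 0.645), and neither did the chaperone list with 6 of 21 higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.645). Replicate 4 of 120 min had the widest spread of all arrays and 3 values at a shared maximum of 15.73. The count at 120 min was 539 without experiment B, 1854 with each array centred on its median (931 higher, 923 lower), 1067 after scaling the arrays to the same spread and 1098 after quantile normalization.

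**Figure D3:**
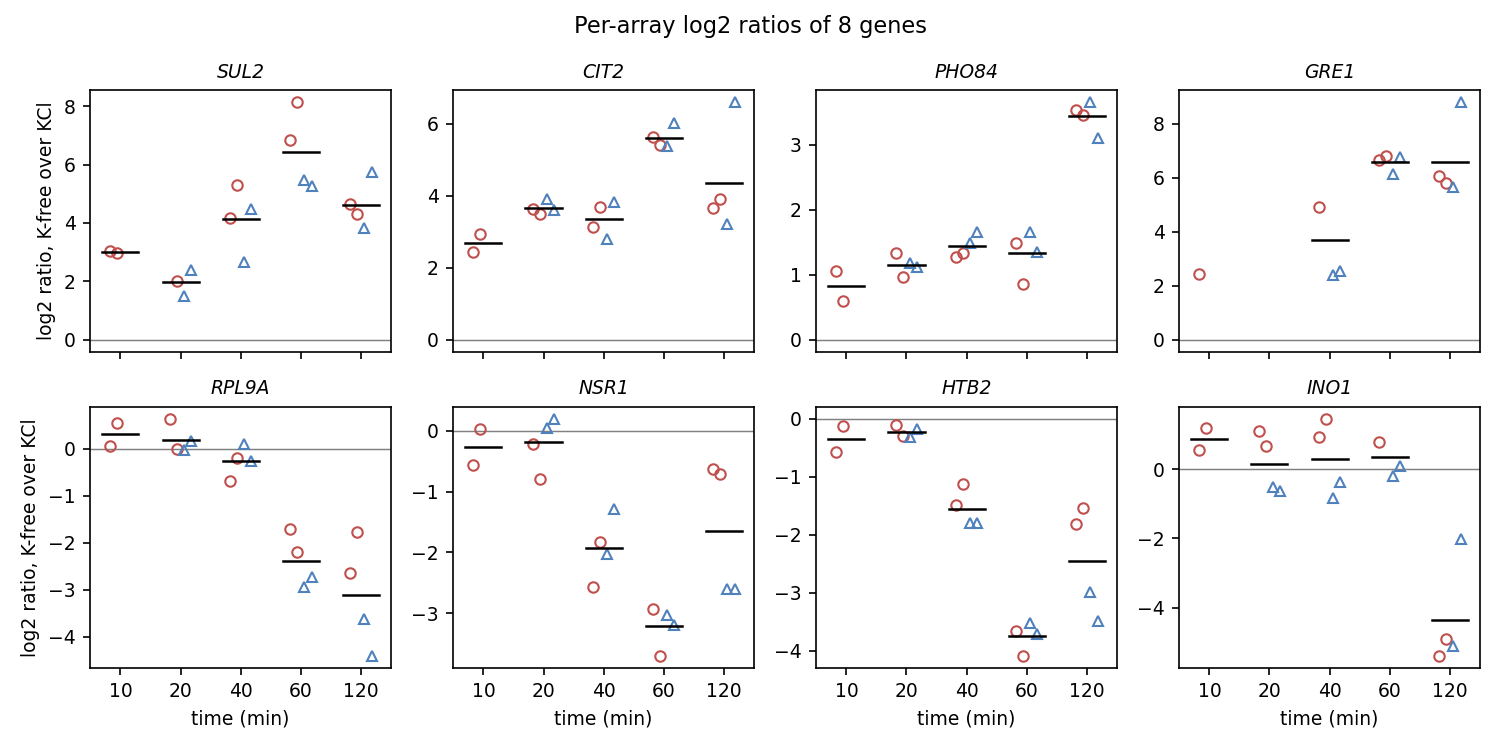
Log2 ratios of 8 genes on each array (y axis) at each time point (x axis, min), with circles for the arrays of experiment A, triangles for those of experiment B and a bar for the mean where it was tested. PHO84 had means of 1.15 at 20 min and 3.44 at 120 min, and INO1 had a mean of -4.35 at 120 min.

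Other fixed lists were also tested. RNA polymerase I and III subunits had 3 of 17 lower at 40 min, 5 when adjusted over the list alone (median -0.56, camera adjusted p = 0.000453; adjusted p = 0.464 with an estimated correlation), and 8 of 16 lower at 120 min, 9 when adjusted over the list alone (median -0.70, camera adjusted p = 0.0146; adjusted p = 0.537 with an estimated correlation). Mitochondrial respiratory chain genes had 6 of 28 higher at 40 min, 10 of 27 at 60 min and 10 of 29 at 120 min, and 9, 10 and 9 when adjusted over the list alone, with medians of 0.55 (0.36 without replicate 3), 0.52 and 0.27 (0.05 in experiment A and 0.64 in B; camera adjusted p = 2.06e-05, 0.0129 and 0.0259; adjusted p = 0.477, 0.575 and 0.581 with an estimated correlation). Oxidative stress genes had 9 of 24 higher and 2 lower at 60 min, the same numbers when adjusted over the list alone. The list median was 0.49 (camera adjusted p = 0.00549; adjusted p = 0.463 with an estimated correlation). Glycolysis and fermentation genes had 3 of 22 higher at 40 min, also when adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.00549; adjusted p = 0.463 with an estimated correlation). At 120 min they had 3 of 20 higher and 9 lower, 5 and 9 when adjusted over the list alone, and did not pass (median -0.36, camera adjusted p = 0.242). The mean and the median differed in sign for this list and for sporulation genes at 120 min. For chaperones at 120 min and for the iron and Gcn4-type lists at 60 min the test and the mean pointed the other way from the median. The G2 and M phase list had 7 of 23 lower at 120 min, also when adjusted over the list alone (camera adjusted p = 0.0742), the nitrogen catabolite list 7 of 25 higher and 4 lower, also when adjusted over the list alone (0.213), and the purine list 4 of 19 higher and 3 lower, also when adjusted over the list alone (0.736). Zinc and copper genes had 1 of 10 higher and 2 lower at 120 min, 1 and 1 when adjusted over the list alone (0.547), and sporulation genes 0 of 6 higher and 2 lower, also when adjusted over the list alone (0.646). Of the alpha-mating-type genes 1 was tested at 120 min, too few for a list test. Of 146 pairs of a list and a time point 79 passed an adjusted p of 0.05 and 0 did with an estimated correlation, where the lowest adjusted p was 0.257; 1 of the 79 had no such test. With only genes measured on all 18 arrays, the respiratory chain did not pass at 60 and 120 min (adjusted p = 0.0872 and 0.0562), nor did calcineurin-type targets (0.146) or polymerase subunits (0.0525) at 120 min. In fry, a test of whether genes of a list move 1 way on balance, 46 of the 79 passed.

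Transport and housekeeping genes were followed at all time points. Of the potassium and monovalent cation transport list 2 of 15 were higher at 40 min, 6 of 14 higher and 1 lower at 60 min and 6 of 15 higher at 120 min, and when adjusted over the list alone these were 3, then 6 and 1, and 6. At 60 min the phosphatase-related genes VHS3 (2.25) and PPZ2 (1.59) and the kinase genes PTK2 (2.00) and HAL5 (1.29) rose, and HAL1 rose at 120 min (2.34); the plasma membrane proton pump gene PMA1 rose at 60 min (0.79, adjusted p = 0.0437) but did not pass without replicate 4 (adjusted p = 0.0532). The list passed at 120 min by a narrow margin (median 0.49, camera adjusted p = 0.0476; adjusted p = 0.476 with an estimated correlation) and no longer did with each array centred (0.0551), with the other pairing (0.0875), without replicate 4 of 120 min (0.0547, median 0.24) or without replicate 3 of 40 min (0.051). TRK1, the main potassium uptake transporter, was not past the threshold at any time point and had 0.20 ± 0.19 at 120 min (adjusted p = 0.425). TRK2, where measured, did not pass either (0.49, adjusted p = 0.144 at 120 min), and the sodium pump gene ENA1 was measured on too few arrays to be tested. The reference genes had 0 calls at 10, 20 and 40 min and 1 lower gene at 60 and at 120 min, with ACT1 at -0.32 (adjusted p = 0.178) at 120 min. HIS3 (0.52, adjusted p = 0.242) and URA3 (0.99, adjusted p = 0.0995), deleted in this strain, did not pass at 120 min, and LEU2 and MET17 were tested at 10 min alone. At 10 min the 4 deleted genes had a median of 0.48 (camera adjusted p = 0.0186, with no estimated correlation run). Since these genes are listed as deleted in this strain, a list call of this size need not reflect messages of its genes, at 10 min or later. URA3 at 120 min (0.99, not past the threshold) lay above the median of the cation transport list (0.49), which passed. The phosphate list had a similar median at 10 min (0.46). What gave the signal was not tested.

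All 20 genes higher at 20 min were also higher at 40 min. Of 236 genes higher at 40 min and tested in both, 231 were higher at 60 min, and 562 genes were higher and 644 lower at both 60 and 120 min. The calls share a spread per gene across time points, so these overlaps were not set against chance. Between the means of 60 and 120 min the correlation across genes was 0.82, and between 20 and 120 min 0.338. In the test for any difference among 20, 40, 60 and 120 min, 525 of 3714 genes passed. From 20 to 120 min 217 genes rose and 412 fell of 3978 tested. The largest rises were HSP26 (6.21 ± 0.90), NQM1 (4.72 ± 0.72), SSA4 (3.76 ± 0.44), AGA1 (3.52 ± 0.36) and ALD3 (3.41 ± 0.64), with adjusted p from 0.0152 to 0.0176. The largest falls were INO1 (-4.49 ± 0.79), YAR073W (-3.60 ± 0.41), RPL9A (-3.31 ± 0.57), RPS22A (-3.28 ± 0.58) and RPS9B (-3.27 ± 0.66), with adjusted p from 0.0155 to 0.0199; INO1 was at -5.26 without replicate 4 of 120 min, and at -3.72 without replicate 3, where it did not pass (adjusted p = 0.0597). Without 1 of the experiments at 20 or 120 min the 629 genes of this difference became 0 to 1000. The 525 genes that differ among the 4 time points became 0 without experiment A of 20 min or B of 60 min, 1 without B of 20 min, 126 or 22 without A or B of 40 min, 808 without A of 120 min, 285 without replicate 2 of 60 min and 330 without replicate 3 of 120 min.

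Differences between neighbouring time points, chosen after seeing the data, gave 0 genes past the threshold at each of the 4 steps in limma, with 15, 382, 847 and 792 at an unadjusted p under 0.05. As lists, ribosome biogenesis moved by a median of -0.96 from 20 to 40 min (camera adjusted p = 1.12e-24) and by 0.81 from 60 to 120 min (camera adjusted p = 3.23e-11), and ribosomal proteins by -1.56 from 40 to 60 min (camera adjusted p = 3.78e-45). The proteasome list moved by 0.37 from 40 to 60 min and by -0.52 from 60 to 120 min. None of these passed with an estimated correlation, where the lowest adjusted p was 0.66.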

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

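The test of whole-array centring and the test of a brightness bias in the last paragraph here were chosen only after the result was seen, and the test without replicate 3 of 40 min was not planned.

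Single arrays stood apart from the other 3 of their time point for 10 values, by Dixon's criterion, among 150 groups of 4 arrays tested; chance gives about 1 in 20 groups, here 7.5. At 20 min STR3 was at 5.31 on replicate 4 and at 3.24 to 3.54 on the others. At 40 min DBP2 was at -2.72 on replicate 3 and at -2.16 to -2.05 on the others. At 60 min HMX1 was at 2.93 on replicate 2 and at 3.86 to 4.02 on the others, and the median of all genes was -0.237 on replicate 2 and -0.03 to 0.006 on the others. At 120 min replicate 4 held 4 of these values. GRE1 was at 8.78 there and at 5.67 to 6.06 on the others, NQM1 at 6.50 and at 4.24 to 4.38, PDC6 at 6.67 and at 2.72 to 3.31, and INO1 at -2.01 and at -5.39 to -4.90. On replicate 3 of 120 min AGA1 was at 5.47 against 4.16 to 4.25, and SER3 at 3.69 against 3.48 to 3.49.

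Responses that differ between time points were also singled out. The F test over 20, 40, 60 and 120 min passed 525 genes (0 to 808 with 1 experiment left out), and the contrast of 120 with 20 min passed 629 (0 to 1000). The rises from 20 to 120 min were 6.21 for HSP26 (from -1.55 to 4.66), 4.72 for NQM1, 3.76 for SSA4, 3.52 for AGA1 and 3.41 for ALD3. The falls were -4.49 for INO1 (-3.72 and not past the threshold without replicate 3 of 120 min, -5.26 without replicate 4), -3.60 for YAR073W, -3.31 for RPL9A, -3.28 for RPS22A and -3.27 for RPS9B.

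Ribosome biogenesis genes lay below ribosomal protein genes at 40 min and above them at 120 min: the difference of the list medians averaged -0.838 at 40 min, 0.05 at 60 min and 1.32 at 120 min. Centring or scaling of whole arrays cannot turn the sign of such a difference, so the outcome of this test was fixed by the pattern itself. The lowest 120 min array lay 1.44 above the highest 40 min array. Normalization that depends on intensity within an array was not tested. A bias that follows brightness would be shared by abundant messages. At 120 min the glycolysis median lay at least 1.64 above the ribosomal protein median in either experiment. This argues against such a bias as the whole account of 120 min. From 60 to 120 min, though, glycolysis genes moved by a median of -0.66 and ribosomal protein genes by -0.47. Biogenesis genes moved by 0.81, so a share of such a bias in this step is not excluded. At 40 min the glycolysis and ribosomal protein medians were 0.30 and -0.57 in experiment A and 0.32 and 0.08 in experiment B. For 40 min such a bias was therefore not argued against. Part of the 40 min value rests on replicate 3 (-1.52); the other arrays were at -0.322, -0.792 and -0.717, with a mean of -0.61 and an SD of 0.253, which leaves the size at 40 min open. No biological explanation of the order was tested.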

How the results depend on the processing

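The fits of single time points, those without values at the shared maximum, and those without replicate 3 of 40 min or replicate 4 of 120 min for lists and for counts at other time points, were chosen only after the result was seen; the other settings were planned. With the other pairing limma called 4 genes at 10 min, 88 at 20 min, 1244 at 40 min, 1758 in the F test and 1548 between 20 and 120 min, against 0, 21, 420, 525 and 629. In the same order each array as a replicate gave 39, 113, 1340, 1941 and 1527, a random block 7, 68, 936, 1408 and 1132, and a dye term 22, 94, 1280, 1901 and 1476. Each array as a replicate and the dye term count dye swaps of the same RNAs as separate samples. These are technical repeats and not more samples. Scaled to the same spread, the counts were 76 at 10 min, 312 at 20 min, 701 at 40 min, 1157 at 60 min, 1067 at 120 min, 126 in the F test and 374 between 20 and 120 min. Quantile normalization gave 115, 376, 829, 1145 and 1098 at the 5 times and 199 in the F test; the cause was not tested. At an adjusted p of 0.01 there were 7, 46, 1234 and 816 genes at 20 to 120 min, 0 in the F test (limma, 1353 at an unadjusted p under 0.05) and 1 between 20 and 120 min. Requiring 2-fold as well left 1157 at 60 min and 1026 at 120 min, and 2-fold on every array without a test gave 61, 32, 199, 700 and 488, and 221 between 20 and 120 min. Time points fitted alone gave 65 at 20 min, 996 at 40 min, 1350 at 60 min and 646 at 120 min. Leaving out arrays or experiments gave 0 genes at 10 min, 1 to 23 at 20 min, 24 to 475 at 40 min, 990 to 1968 at 60 min, 539 to 1919 at 120 min, 0 to 808 in the F test and 0 to 1000 between 20 and 120 min. Where an experiment was left out, the lone one left is assumed to vary like those of other time points, and at 10 min leaving out its only experiment leaves no value. The replicate block gave 0, 23, 385, 1941 and 1889 genes at the 5 times, 403 in the F test and 576 between 20 and 120 min, all within 1.5 times. Deviations of same-numbered experiments correlated with r = 0.21 between 20 and 40 min, 0.43 between 60 and 120 min and -0.046 to -0.18 otherwise. The numbers were not taken to pair samples across time, and the main fit treats the experiments as independent. A shared culture or batch at 20 and 40 min or at 60 and 120 min is not excluded. Centring, the filters and the robust prior kept counts within 1.5 times. Of 79 list calls 0 passed with an estimated correlation, 17 were lost with genes on all 18 arrays and 6 with the other pairing. Medians of the called lists kept their sign under centring, scaling and quantile normalization, but their sizes moved. The sulfur list rose from 1.35 at 20 min to 2.54 at 60 min as deposited. It went from 2.34 to 1.62 with arrays scaled to the same spread and from 2.48 to 1.75 after quantile normalization. INO1 at 60 min, 0.36 and not called, ran from -0.058 without replicate 1 or experiment A to 0.776 without experiment B of 60 min; the cause was not tested.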

Other observations

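Both gene lists described here were chosen after their values were seen, so all tests in this part are tests on the data that drew attention to them.

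Genes of the pheromone response, which haploid cells of a-type use in mating, were higher at 120 min. Of 22 measured members 16 rose and 1 fell, the same numbers when adjusted over the list alone. The median was 1.5 (camera adjusted p = 3.36e-11; adjusted p = 0.408 with an estimated correlation). AGA1 stood at 4.52, FIG2 at 3.35, the cell fusion gene FUS1 at 2.98 and the transcription factor gene KAR4 at 2.68. At 60 min 12 of 19 rose and 0 fell, 14 when adjusted over the list alone. The median was 1.11 (camera adjusted p = 3.84e-05; adjusted p = 0.408 with an estimated correlation), and at 40 min 5 of 22 rose, 7 when adjusted over the list alone.

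Phospholipid synthesis genes with an inositol-sensitive promoter element were lower at 120 min: 11 of 13 fell and 0 rose, 12 fell when adjusted over the list alone. The median was -1.19 (camera adjusted p = 3.35e-07; adjusted p = 0.408 with an estimated correlation). They include INO1 (-4.35, or -3.58 without replicate 3 and -5.12 without replicate 4) and the phosphatidylserine synthase gene CHO1 (-2.14). At 60 min the same list had 3 higher and 4 lower members, 3 and 5 when adjusted over the list alone, and did not pass (median -0.32, camera adjusted p = 0.667), with INO1 at 0.36 (adjusted p = 0.616), -0.058 without replicate 1 or experiment A and 0.776 without experiment B.

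For the pheromone genes, an effect of the 120 min array with clipped values is argued against by a median of 1.62 over the other 3 arrays, and an effect of a single experiment by the lower experiment's median of 1.23. Cells of the other mating type could not be tested, since 1 alpha-type gene was measured well enough. No biological explanation of the pattern was tested.

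For the phospholipid genes, the list's median change from 60 to 120 min lay -1.26 from that of all genes, which centring of whole arrays would not give. Every 60 min array had a list median at least 0.285 above that of every 120 min array, which argues against single arrays. No biological explanation was tested here either.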
